A study of Mus musculus with 15 samples.

How the data were processed

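RNA was measured in the epithelium and in the mesenchyme of embryonic mouse salivary glands of the ICR strain. The submandibular gland (SMG) was collected at embryonic day 11.5 and the parotid gland (PG) at embryonic day 12. The groups were SMG epithelium (n = 4), SMG mesenchyme (n = 4), PG epithelium (n = 3) and PG mesenchyme (n = 4), 15 libraries in all, and each library was assigned to its group by its title. Per the labels' protocols the replicates were independent biological ones, RNA was isolated with TRIzol, and RNA integrity was above 8.7 in every sample. Full-length cDNA was made with a SMART-Seq v4 low-input kit, libraries with Nextera XT, and the pool was sequenced on a HiSeq 1500. How the layers were separated, how many glands went into a sample and the order of dissection are not given in the sources used here. The gland and the embryonic day change together, so every comparison between glands is also one between stages.

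The authors deposited a table of whole-number counts per Ensembl gene and a second table of CPM, counts scaled by library size. The submitters' processing notes name STAR 2.5.2a, DESeq2, edgeR and limma and the builds GRCm38.p3 and mm10, without saying which tool made which table. The counting program, its strand setting and the annotation release are not given in the sources used here. The cDNA kit does not mark the strand, so reads of a gene and of a transcript on the opposite strand cannot be told apart. Of 476 genes named by the rule below, 135 share exon bases with another annotated gene, 119 of them on the opposite strand. They include Foxe1, Hpca, Hand2, Shox2, Irx3, Rarb, Nid2, Ednra, Fgfr2 and Cyp2s1, whose counts may hold reads of the neighbour. Keratin paralogs (Krt6a with Krt6b, Krt14 and Krt17 with Krt16) and the globins are close in sequence, and the split of reads between them is uncertain.

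The count table held 48709 genes and 92 rows for ERCC spike-in RNA. Spike-in rows were left out of library sizes and tests, and they drew 371 to 1314 counts per library, at most 0.0054% of the total. Gene symbols were taken from a name table, in which 48349 of the Ensembl identifiers were found and 360 were not. Coordinates are 1-based and come from the GENCODE M21 annotation of GRCm38. The deposited CPM table held 24675 rows, 23 of them spike-ins, and its values were whole reads divided by 1 constant per library (100.00% of the values within 0.001 reads). It served only for alternatives. No per-library column was left unmapped.

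Total gene counts per library ran from 20561142 to 29552734, so that 1 read is worth a median of 0.039 CPM. A gene with no count in any library of a group is given as a bound from a floor of 3 counts over that group. For a gene with 1 to 3 counts in a group, the ratio of CPM is given with its 95% counting interval (exact Poisson). These intervals cover counting error only, since PCR copies were not marked with molecular identifiers. CPM in the text are computed from the counts with TMM factors and given as mean ± SD over libraries.

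Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr by group, which left 18940 genes. TMM factors, robust dispersion estimates and the robust quasi-likelihood fit were used, with 1 mean per group and all 15 libraries in 1 fit, so that the 4 groups share an estimate of the spread. The biological coefficient of variation was 0.227. Tests were edgeR's quasi-likelihood F-tests, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Calls were counted again among genes with an absolute log2 change of at least 1. There were 5 comparisons: epithelium against mesenchyme in each gland, PG against SMG in each layer, and the interaction, which asks whether the layer difference differs between the glands. Unless another tool is named, every adjusted p of a gene is from this test. Log2 changes are given ± standard error, as edgeR fitted them with its prior count.

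Altogether 32 gene lists, holding layer identity, gland bud regulators, signalling pathways, matrix, patterning genes, markers of other cell types and technical groups, were tested with camera in limma 3.58.1. The preset inter-gene correlation was 0.01, and p-values were adjusted over the lists of a comparison. Each list was tested again with a correlation estimated from the data. At an adjusted p under 0.05 the estimated correlation left 0, 1, 0, 0 and 0 lists called in the 5 comparisons, in the order given above, and that p is printed beside each list called with the preset one. List members were also adjusted over the list alone.

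Genes named in the text followed a rule. It took the 8 genes of each direction with the largest fitted change among those past the threshold, with a mean CPM of at least 20 in the higher group and no overlap between the libraries compared. It then took up to 4 changed members of each list with a mean CPM of at least 5, up to 2 in the opposite direction and up to 2 unchanged ones. A further 13 genes were always included. Predicted gene models, Y-linked genes and Xist were left out of the first part. Some genes that the rule took are not reported here. The groups, tests, gene lists, this rule and most alternatives were chosen before the data were examined.

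The alternatives were median-ratio size factors, no filter on low counts, the Wald test of DESeq2 1.42.0, limma-trend on log2 of the deposited CPM plus 1, a fit of the compared groups alone, each library left out in turn, and the replicate number as a block. The test on reads recovered from the deposited CPM, the fit without both PG epithelium replicate 2 and PG mesenchyme replicate 1, and the similarity of comparisons with each library left out were chosen after seeing the data.

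The share of the other layer's RNA that a library appears to hold was estimated from the identity lists. It is the median, over the markers of the other layer with at least 20 CPM there, of the library's CPM divided by the mean CPM of the other layer of the same gland. When RNA was mixed at 2, 5 and 15% in simulated libraries, the estimate was 2.57, 5.55 and 15.7%, and 0.346% with none mixed. The fits were tested on simulated counts drawn from the real means and library sizes, with 200 genes changed. At 4-fold, edgeR recovered 98.5% of the changed genes in the SMG layer comparison, 93.9% in the PG layer comparison, 92.4% between the epithelia, 98.5% between the mesenchymes and 86.4% in the interaction. At 1.5-fold it recovered 44.8, 46.3, 50.7, 41.8 and 10.4%, in the same order, with 18450 or 18459 genes in each simulation.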

Results

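Bulk RNA sequencing was carried out on the epithelium and the mesenchyme of mouse submandibular glands (SMG) at embryonic day 11.5 and of parotid glands (PG) at embryonic day 12. At these stages the gland epithelium forms a bud within condensing mesenchyme. There were 4 libraries each of SMG epithelium, SMG mesenchyme and PG mesenchyme and 3 of PG epithelium. Total gene counts ran from 27285248 to 29552734 in SMG epithelium, 22762834 to 25185378 in SMG mesenchyme, 24128898 to 26514342 in PG epithelium and 20561142 to 26006021 in PG mesenchyme. Between 24422 and 26087 genes had at least 1 read in a library, and the 10 most counted genes took 2.27 to 3.31% of the counts. Replicates of a group correlated at r = 0.966 to 0.986 across genes (log2 CPM), and every pair differed by more than sampling noise. Principal component 1, with 62.6% of the variance, separated the layers. Component 2 (14.4%) separated the glands in both layers, and component 3 (5.97%) in both with opposite signs. PG epithelium replicate 2 had a score of 67.2 on component 1, against 112.3 and 115.7 in the other libraries of its group.

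**Figure D1:**
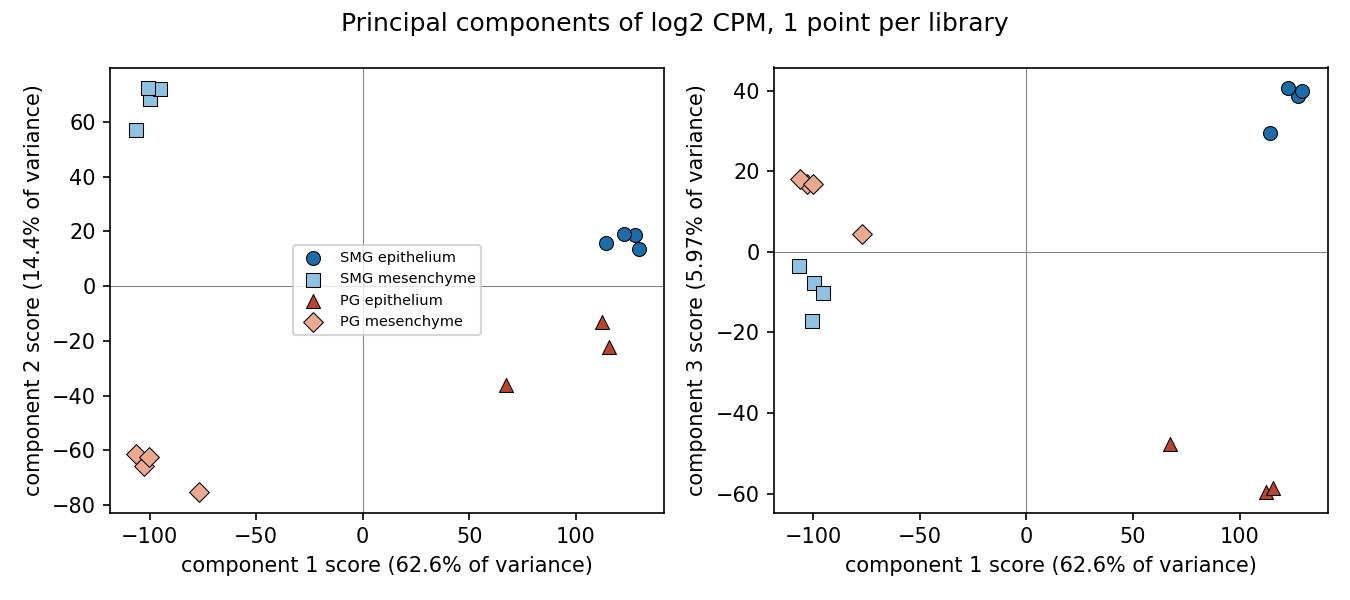
Scores of the 15 libraries on principal components 1 and 2 (left) and 1 and 3 (right) of log2 CPM, with the share of variance on each axis and 1 symbol per group. Epithelium libraries lie at 67.2 to 129.5 on component 1 and mesenchyme libraries below 0.

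Markers of the other layer were measured in every library, relative to their level in that layer of the same gland. Epithelial markers in SMG mesenchyme stood at 0.142 to 0.509% of their SMG epithelium level. In PG mesenchyme the apparent share was 18.3% in replicate 1 and 3.29 to 4.07% in the other 3 libraries. Mesenchymal markers stood at 1.00 to 1.68% in 3 libraries of SMG epithelium and 6.20% in replicate 3, and at 2.00, 6.56 and 2.03% in PG epithelium replicates 1 to 3.

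**Figure D2:**
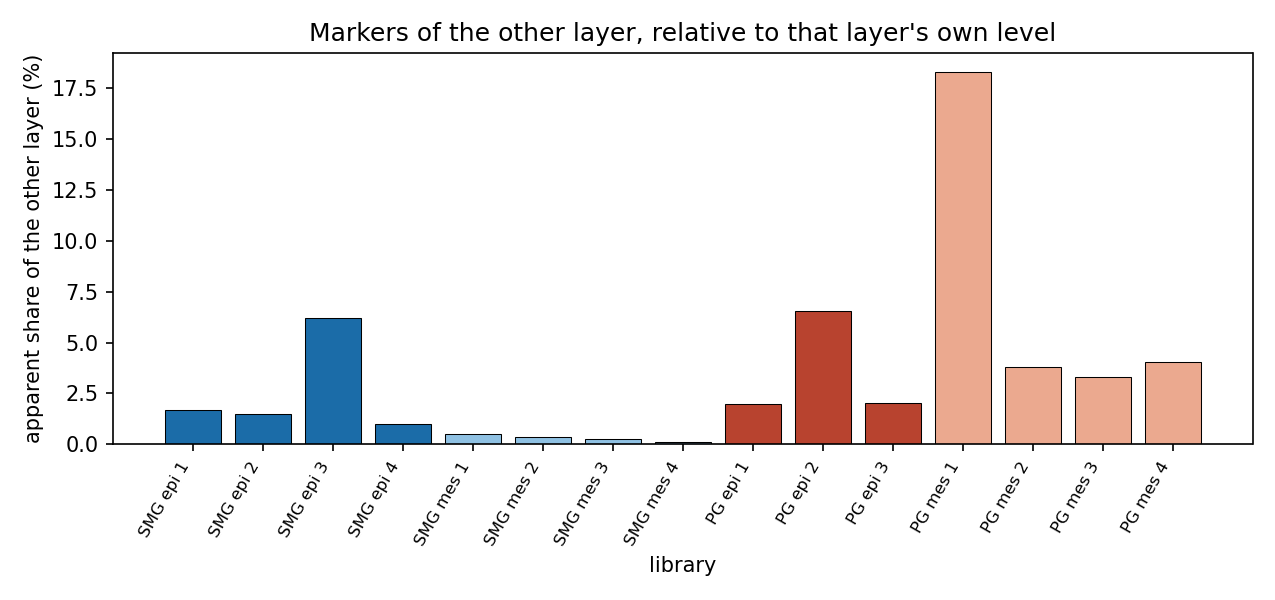
Apparent share of the other layer's RNA in each of the 15 libraries, in percent (bars from 0, coloured by group). PG mesenchyme replicate 1 stands at 18.3%, and the SMG mesenchyme libraries at 0.142 to 0.509%.

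The first comparison asked which genes separate the epithelium from the mesenchyme of the SMG (n = 4 and 4). Ap1m2, a subunit of the clathrin adaptor of polarised epithelia (ENSMUSG00000003309, chromosome 9, 21294275 to 21312337, minus strand), had 98.8 ± 3.00 CPM (SD) in epithelium and 0.0402 ± 0.0464 in mesenchyme, a log2 difference of 11.07 ± 0.87, adjusted p = 2.85e-07. Cdh1, the epithelial adhesion molecule E-cadherin (ENSMUSG00000000303, chromosome 8, 106603351 to 106670246, plus strand), stood at 743 ± 33.7 against 0.908 ± 1.02 CPM (9.66 ± 1.02, adjusted p = 4.76e-06). In the other direction Fgf10, the mesenchymal ligand required for salivary bud outgrowth (ENSMUSG00000021732, chromosome 13, 118669791 to 118792115, plus strand), fell from 257 ± 87.9 CPM in mesenchyme to 0.366 ± 0.300 in epithelium (-9.43 ± 0.79, adjusted p = 5.91e-07). Aldh1a2, which makes retinoic acid (ENSMUSG00000013584, chromosome 9, 71215789 to 71296243, plus strand), went from 635 ± 168 to 1.46 ± 1.26 CPM (-8.76 ± 0.90, adjusted p = 3.77e-06). Other leading epithelial genes were the tight junction gene Cldn8 (9.73 ± 0.88) and the protease gene St14 (9.59 ± 0.86). The ETS factor gene Ehf and the keratin gene Krt6a had 2 counts in all of SMG mesenchyme, and their CPM ratios were 1589 (95% counting interval 440 to 13120) and 1941 (95% counting interval 537 to 16025). Endothelial Cdh5 (-9.72 ± 1.01), Kdr (-9.42 ± 0.99) and Emcn (-9.11 ± 0.95) and the muscle actin gene Actc1 (-9.01 ± 1.37) led the mesenchymal side.

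All 36 tested members of the epithelial identity list were higher in SMG epithelium (camera adjusted p = 1.0e-23, adjusted p = 0.33 with an estimated correlation), Epcam among them (7.06 ± 0.72). Of 36 mesenchymal identity genes, 34 were lower (camera adjusted p = 2.2e-16, adjusted p = 0.28 with an estimated correlation), including Prrx1 (-7.33 ± 0.92), Pdgfra (-6.83 ± 0.91), Twist1 (-6.40 ± 0.84) and Vim (-3.70 ± 0.27). Salivary bud regulators were 25 higher and 4 lower of 32 (camera adjusted p = 5.1e-07, adjusted p = 0.16 with an estimated correlation). Foxa1 (8.63 ± 0.43), Barx2 (7.77 ± 0.67), Tfap2b (6.72 ± 0.55) and Sox9 (4.99 ± 0.36) rose, and Cited1 fell (-5.99 ± 0.33). Sox10, a factor of salivary acinar progenitors and of neural crest, stood at 31.5 ± 6.01 and 28.3 ± 15.3 CPM in epithelium and mesenchyme (adjusted p = 0.749). Interstitial matrix genes were 3 higher and 30 lower of 36 (camera adjusted p = 3.9e-12, adjusted p = 0.18 with an estimated correlation), Col6a1 (-6.38 ± 0.86) and Col1a2 (-6.21 ± 0.53) among them. Col14a1 rose (5.28 ± 0.46). Basement membrane genes were 15 higher and 9 lower of 30 without a call for the list (camera adjusted p = 0.060). It was called with median-ratio size factors (adjusted p = 0.0472), with both PG epithelium replicate 2 and PG mesenchyme replicate 1 left out (0.0165) and without SMG epithelium replicate 1, 2 or 4 (0.0255 to 0.0437), against at most 0.112 with another library left out. The laminin chain gene Lama3 (7.67 ± 0.58) was epithelial, and Lama4 (-6.59 ± 0.65) and Nid2 (-5.87 ± 0.35) mesenchymal. The interstitial matrix count adjusted over the list alone was 3 higher and 31 lower, and the other counts of this paragraph were the same.

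Among signalling lists, BMP and TGF-beta genes were 8 higher and 19 lower of 37 (camera adjusted p = 0.015, adjusted p = 0.33 with an estimated correlation). Tgfbi (-6.18 ± 0.66), Bmp2 (-4.74 ± 0.33) and Bmp4 (-3.12 ± 0.45) fell. EDA, EGF and neuregulin genes were 10 higher and 2 lower of 19 (camera adjusted p = 0.0097, adjusted p = 0.33 with an estimated correlation). Edar (4.58 ± 0.45) and Tgfa (3.14 ± 0.48) were among the epithelial ones. The WNT list went both ways, 13 higher and 20 lower of 44 (camera adjusted p = 0.97). The ligand genes Wnt6 (8.90 ± 0.59), Wnt4 (8.54 ± 0.47) and Wnt10a (8.43 ± 0.55) were among its epithelial members. FGF genes were 17 higher and 9 lower of 33 (camera adjusted p = 0.055, 0.0463 and 0.0432 without SMG epithelium replicate 1 or 4 and at most 0.0685 without another library, 0.0455 with median-ratio factors and 0.0153 without both PG epithelium replicate 2 and PG mesenchyme replicate 1), with Fgf7 mesenchymal (-6.53 ± 0.50) and the receptor gene Fgfr2 epithelial (4.12 ± 0.26). Shh had 21.1 times the CPM of mesenchyme in epithelium, a ratio with a 95% counting interval of 5.84 to 174. The Notch ligand genes Dll4 (-7.60 ± 0.73) and Jag2 (5.35 ± 0.35) and the retinoid genes Aldh1a1 (6.23 ± 0.52) and Rdh10 (-3.83 ± 0.37) took opposite sides. Their lists had no call (camera adjusted p = 0.11 and camera adjusted p = 0.21). Adjusted over the list alone, the counts were 8 higher and 20 lower for BMP and TGF-beta, 10 higher and 4 lower for EDA, EGF and neuregulin, 14 higher and 20 lower for WNT and 18 higher and 10 lower for FGF genes.

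Markers of endothelial, macrophage, muscle and erythroid cells lay mainly in the mesenchyme. Of 19 endothelial markers all 19 were lower in SMG epithelium (camera adjusted p = 6.6e-11, adjusted p = 0.33 with an estimated correlation), as were 20 of 20 macrophage markers (camera adjusted p = 9.9e-09, adjusted p = 0.33 with an estimated correlation). Also lower were 22 of 24 muscle markers (camera adjusted p = 5.5e-06, adjusted p = 0.51 with an estimated correlation) and 13 of 14 erythroid markers (camera adjusted p = 0.0020, adjusted p = 0.51 with an estimated correlation). Examples are Csf1r (-3.59 ± 0.52), Myog (-7.83 ± 1.24, and -11.78 without SMG epithelium replicate 2) and embryonic globin Hbb-y (-3.65 ± 0.69). Periderm and surface keratinocyte markers were 17 higher and 1 lower of 18 (camera adjusted p = 4.4e-06, adjusted p = 0.33 with an estimated correlation), with Sfn at 9.18 ± 0.79. Distal or oral jaw patterning genes were 4 higher and 17 lower of 24 (camera adjusted p = 0.0095, adjusted p = 0.52 with an estimated correlation). Hand2 (-6.30 ± 0.84), Dlx5 (-6.90 ± 0.49) and Alx4 (-8.32 ± 0.64) were mesenchymal and Nkx2-3 (5.88 ± 0.71) epithelial. Glycolysis and hypoxia genes were 21 higher and 5 lower of 29 (camera adjusted p = 1.9e-05, adjusted p = 0.33 with an estimated correlation). G2/M genes were 23 higher and 1 lower of 52 (camera adjusted p = 0.017, adjusted p = 0.73 with an estimated correlation) and cholesterol synthesis genes 14 higher and 3 lower of 24 (camera adjusted p = 0.025, adjusted p = 0.59 with an estimated correlation). The glycolysis genes Aldoc (3.16 ± 0.27) and Ldha (1.63 ± 0.14) were among them. These counts were the same when adjusted over the list alone. The call of the cholesterol list was lost with both PG epithelium replicate 2 and PG mesenchyme replicate 1 left out of the fit (adjusted p = 0.0601), and its adjusted p was 0.0112 to 0.0461 with 1 library left out.

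In all, 4765 genes were higher and 5061 lower in SMG epithelium, 51.9% of the 18940 tested (edgeR, adjusted p under 0.05), and 2161 and 3169 of them by an absolute log2 change of at least 1. In 6 lists without a call the median, the mean and the camera test differed in sign. The Notch list, for example, had a median log2 difference of 0.23, a mean of -0.17 and a test in the upward direction.

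**Figure D3:**
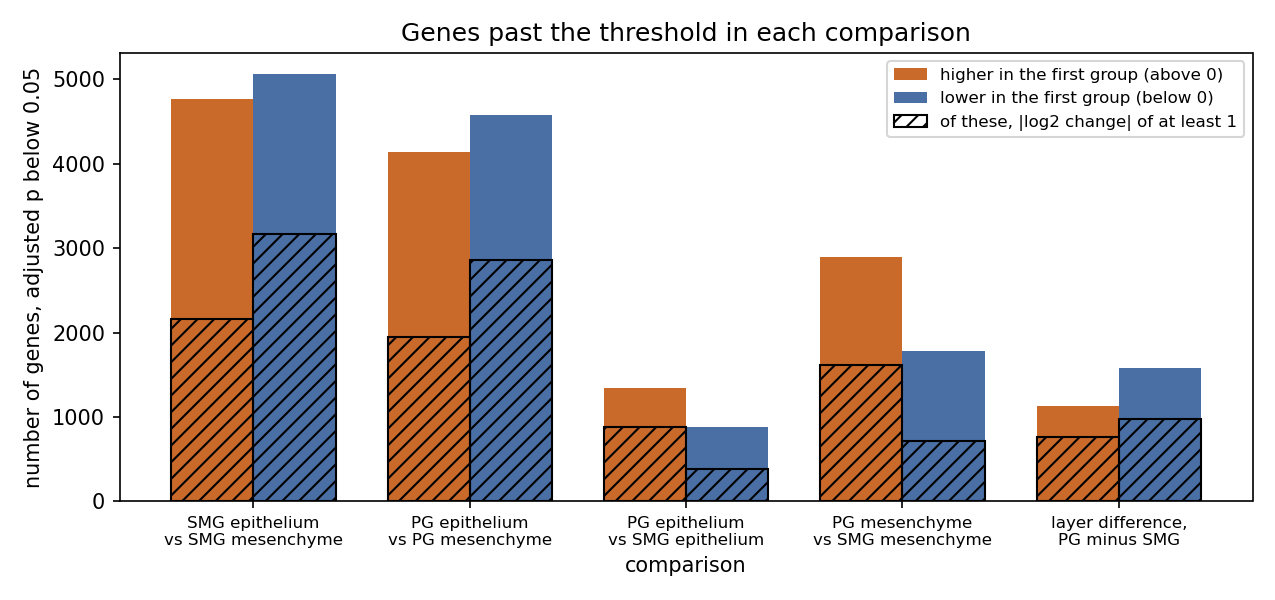
Number of genes past an adjusted p of 0.05 in each of the 5 comparisons, higher (above 0) and lower (below 0), with bars from 0 and the hatched part holding genes with an absolute log2 change of at least 1. The layer comparisons have 9826 (SMG) and 8721 (PG) genes, the gland comparisons 2221 (epithelium) and 4678 (mesenchyme), and the interaction 2705.

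The second comparison put the same question to the PG (epithelium n = 3, mesenchyme n = 4). On the mesenchymal side Kera, a matrix proteoglycan gene (ENSMUSG00000019932, chromosome 10, 97606879 to 97613692, plus strand), had 0.413 ± 0.502 CPM in epithelium and 263 ± 26.4 in mesenchyme (-9.27 ± 0.62, adjusted p = 1.56e-07). The T-box gene Tbx18 (ENSMUSG00000032419, chromosome 9, 87702800 to 87731260, minus strand) went from 321 ± 123 CPM in mesenchyme to 0.684 ± 0.429 (-8.86 ± 0.73, adjusted p = 9.61e-07). The LIM homeobox gene Lhx8 (ENSMUSG00000096225, chromosome 3, 154306294 to 154330659, minus strand) went from 323 ± 47.8 to 0.855 ± 1.41 CPM (-8.54 ± 0.90, adjusted p = 7.83e-06, and -12.83 without PG epithelium replicate 2). The receptor gene Avpr1a and the kinase gene Dgkb had 1 to 3 counts in PG epithelium, and their CPM ratios of mesenchyme to epithelium were 1192 (95% counting interval 408 to 5780) and 544 (95% counting interval 186 to 2638). On the epithelial side stood Hpca, a neuronal calcium sensor gene (5.45 ± 0.34, adjusted p = 5.43e-08), with 59.0 ± 25.4 against 1.35 ± 0.661 CPM. Ehf was at 5.35 ± 0.91, and at 8.27 without PG mesenchyme replicate 1. Fgf10 differed by -7.09 ± 0.81, Epcam by 3.88 ± 0.63 and Cdh1 by 4.07 ± 0.77.

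All 36 epithelial identity genes were higher in PG epithelium (camera adjusted p = 3.6e-16, adjusted p = 0.22 with an estimated correlation), beside the apparent epithelial share of 3.29 to 18.3% in the PG mesenchyme libraries. Esrp1, a splicing regulator of epithelia, differed by 4.13 ± 0.61. Mesenchymal identity genes were 0 higher and 35 lower of 36 (camera adjusted p = 2.0e-18, adjusted p = 0.15 with an estimated correlation). They include Osr2 (-7.33 ± 0.76), Tcf21 (-7.13 ± 0.76), Prrx1 (-6.99 ± 1.03), Vim (-3.15 ± 0.29) and Twist1 (-5.51 ± 0.89, and -8.29 without PG epithelium replicate 2). Salivary bud regulators were 21 higher and 3 lower of 32 (camera adjusted p = 9.6e-07, adjusted p = 0.039 with an estimated correlation), the 1 list of this comparison whose call held with the estimated correlation. Its members Barx2 (4.40 ± 0.53), Foxc1 (4.28 ± 0.45), Tfap2a (4.07 ± 0.51), Sox9 (3.54 ± 0.34) and Sox10 (3.19 ± 0.40) rose and Cited1 fell (-2.95 ± 0.33). Interstitial matrix genes were 3 higher and 29 lower of 36 (camera adjusted p = 3.2e-11, adjusted p = 0.15 with an estimated correlation), with Col3a1 (-6.53 ± 1.26) and Lox (-6.45 ± 0.94). Basement membrane genes were 15 higher and 8 lower of 30 (camera adjusted p = 0.0080, adjusted p = 0.44 with an estimated correlation), with Col4a6 epithelial (4.57 ± 0.33) and Lama4 mesenchymal. With p adjusted over the list alone, bud regulators were 23 higher and 3 lower and matrix genes 3 higher and 30 lower, with no other change in this paragraph.

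BMP and TGF-beta genes were 6 higher and 22 lower of 37 (camera adjusted p = 0.0035, adjusted p = 0.22 with an estimated correlation). Bmp7 (2.86 ± 0.23) and the antagonist gene Nog (1.94 ± 0.31) were epithelial. EDA, EGF and neuregulin genes were 9 higher and 3 lower of 19 (camera adjusted p = 0.024, adjusted p = 0.37 with an estimated correlation), with Edar (4.38 ± 0.44) and its adaptor gene Edaradd (2.65 ± 0.21). WNT genes were 15 higher and 22 lower of 44 (camera adjusted p = 0.30). Their adjusted p was 0.0317 to 0.834 with 1 library left out, the lowest without PG epithelium replicate 2, and 0.0298 without both that library and PG mesenchyme replicate 1. The antagonist gene Dkk2 (-6.15 ± 0.96) and the agonist gene Rspo2 (-6.31 ± 0.94, and -11.02 without PG epithelium replicate 2) were mesenchymal, and Wnt7a (4.18 ± 0.92) and Wnt9b (3.95 ± 0.43) epithelial. FGF genes were 16 higher and 14 lower of 33 (camera adjusted p = 0.21, and 0.0387 without both libraries), with Fgf18 (-5.32 ± 0.63) and Fgf7 (-4.51 ± 0.55) mesenchymal and Fgfr2 (2.85 ± 0.26) epithelial. The retinoic acid degrading enzyme genes took opposite sides, Cyp26a1 epithelial (4.69 ± 0.47) and Cyp26b1 mesenchymal (-4.59 ± 0.47), in a list with no call (camera adjusted p = 0.54). These counts adjusted over the list alone were 7 higher and 22 lower for BMP and TGF-beta, 16 higher and 22 lower for WNT and 17 higher and 14 lower for FGF genes, and unchanged for EDA, EGF and neuregulin genes.

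Muscle markers were lower in PG epithelium in 24 of 24 cases (camera adjusted p = 2.9e-13, adjusted p = 0.22 with an estimated correlation), with Des (-7.53 ± 0.38), Myog (-7.48 ± 1.06) and Chrna1 (-7.73 ± 0.90). Endothelial markers were lower in 19 of 19 (camera adjusted p = 8.9e-09, adjusted p = 0.22 with an estimated correlation) and macrophage markers in 19 of 20 (camera adjusted p = 1.0e-11, adjusted p = 0.18 with an estimated correlation). Erythroid markers were lower in 10 of 14 (camera adjusted p = 0.015, adjusted p = 0.53 with an estimated correlation), with adjusted p = 0.00240 to 0.0708 with 1 library left out, the highest without PG epithelium replicate 2. Examples are Ptprc (-5.25 ± 0.71), Slc4a1 (-4.66 ± 0.91) and Cdh5 (-5.84 ± 0.87, and -11.37 without PG epithelium replicate 2). Cartilage list genes were 7 higher and 3 lower of 13 (camera adjusted p = 0.0073, adjusted p = 0.22 with an estimated correlation). Col9a3 (4.86 ± 0.40), Col9a1 (4.44 ± 0.36) and Sox9 rose, of which Sox9 also acts in bud epithelium, and Hapln1 fell (-4.85 ± 0.54). Periderm markers were 16 higher and 1 lower of 18 (camera adjusted p = 3.6e-05, adjusted p = 0.22 with an estimated correlation). Distal or oral jaw genes were 6 higher and 12 lower of 24 (camera adjusted p = 0.032, adjusted p = 0.51 with an estimated correlation). Lhx6 (-7.42 ± 0.63), Dlx6 (-6.98 ± 0.54), Hand2 (-6.03 ± 1.09) and Dlx5 (-5.21 ± 0.46) were mesenchymal. Proximal jaw genes were 3 higher and 10 lower of 16 (camera adjusted p = 0.044, adjusted p = 0.44 with an estimated correlation), with Shox2 (-7.88 ± 0.64) and Tbx18 mesenchymal. Their call was lost without PG epithelium replicate 1 or PG mesenchyme replicate 1, 2 or 4 (adjusted p = 0.0507 to 0.145), and with other libraries left out the adjusted p was as low as 9.06e-07.

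Glycolysis and hypoxia genes were 11 higher and 2 lower of 29 (camera adjusted p = 0.0073, adjusted p = 0.44 with an estimated correlation), with the glucose transporter gene Slc2a3 at 2.45 ± 0.23. Their call was lost with both PG epithelium replicate 2 and PG mesenchyme replicate 1 left out (adjusted p = 0.0673), against 0.00151 to 0.0329 with 1 library left out. Of the cell cycle lists, G2/M genes were 23 higher and 0 lower of 52 (camera adjusted p = 0.0080, adjusted p = 0.63 with an estimated correlation) and S phase genes 18 higher and 3 lower of 42 (camera adjusted p = 0.040, adjusted p = 0.53 with an estimated correlation). Differences were small, as for Uhrf1 (0.99 ± 0.17) and Nek2 (0.80 ± 0.13). With 1 library left out these adjusted p were 0.00335 to 0.125 and 0.0222 to 0.198, both highest without PG mesenchyme replicate 1. They were 0.0672 and 0.115 without PG epithelium replicate 1. Adjusted over the list alone, the counts of this and the preceding paragraph were the same. Shh had 84.5 times the CPM of mesenchyme in epithelium (95% counting interval 15.2 to 3336), and did not pass the threshold without PG epithelium replicate 2 (adjusted p = 0.414). In all, 4139 genes were higher and 4582 lower in PG epithelium, 46.0% of those tested, and 1945 and 2859 by an absolute log2 change of at least 1. In 6 lists without a call the median, the mean and the test differed in sign, among them the FGF list (median 0.35, mean -0.05, test upward).

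The third comparison asked which genes separate the PG from the SMG in the epithelium (n = 3 and 4). Cxcl14, a chemokine gene (ENSMUSG00000021508, chromosome 13, 56288643 to 56296551, minus strand), rose from 0.533 ± 0.190 CPM in SMG to 299 ± 220 in PG epithelium (9.12 ± 0.74, adjusted p = 7.62e-06). The Iroquois homeobox genes Irx3 (ENSMUSG00000031734, chromosome 8, 91798525 to 91802067, minus strand), Irx4 and Irx5 (ENSMUSG00000031737, chromosome 8, 92357625 to 92376286, plus strand) rose by log2 6.01 ± 0.43, adjusted p = 1.12e-06, 7.24 ± 0.54 and 5.19 ± 0.45. Irx5 went from 2.70 ± 1.29 to 98.4 ± 12.4 CPM. In the other direction the homeobox gene Tlx1 (ENSMUSG00000025215, chromosome 19, 45150680 to 45156943, plus strand) fell from 122 ± 10.4 to 0.973 ± 0.873 CPM (-6.95 ± 0.45, adjusted p = 5.00e-07). The forkhead gene Foxa1, active in foregut epithelia (ENSMUSG00000035451, chromosome 12, 57540628 to 57546916, minus strand), fell from 111 ± 12.8 to 0.905 ± 0.568 CPM (-6.92 ± 0.43, adjusted p = 3.37e-07). Foxe1 (ENSMUSG00000070990, chromosome 4, 46343609 to 46346412, plus strand) went from 379 ± 30.5 to 23.4 ± 11.7 CPM (-4.02 ± 0.64, adjusted p = 0.00130). Steap4 (7.01 ± 0.97), Otx1 (5.79 ± 0.50) and Lmo1 (5.02 ± 0.51) were further genes higher in PG, and Aldh1a7 (-4.53 ± 0.57), Dmrt2 (-4.45 ± 0.47) and the amine-forming enzyme gene Ddc (-4.11 ± 0.25) were lower. Epcam and Cdh1 did not pass the threshold (log2 -0.23 ± 0.59, adjusted p = 0.866 and -0.92 ± 0.73, adjusted p = 0.494), nor did Pdgfra, Twist1, Sox9, Fgfr2, Fgf10, Shh or Hand2. In a fit of the compared groups alone Cdh1 did, at -0.91 (adjusted p = 3.64e-04), and so did Fgfr2, at 0.46 (0.0255). Without PG epithelium replicate 2 Shh did, at -3.28 (0.0419).

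WNT genes were 20 higher and 2 lower of 44 (camera adjusted p = 9.7e-08, adjusted p = 0.43 with an estimated correlation), and 23 higher and 3 lower adjusted over the list alone. The target gene Sp5 (6.72 ± 0.73) and the ligand genes Wnt7a (4.08 ± 0.90), Wnt3a (3.65 ± 0.73) and Wnt3 (3.32 ± 0.40) rose, and the antagonist gene Dkk3 fell (-1.62 ± 0.17). Interstitial matrix genes were 13 higher and 3 lower of 36 (camera adjusted p = 5.3e-07, adjusted p = 0.58 with an estimated correlation), and 16 higher and 4 lower adjusted over the list alone. Timp3 (3.85 ± 0.34) and Col12a1 (3.19 ± 0.15) rose. Basement membrane genes were 11 higher and 1 lower of 30 (camera adjusted p = 4.5e-04, adjusted p = 0.58 with an estimated correlation), and 13 higher and 1 lower adjusted over the list alone. Smoc1 (3.30 ± 0.39), Frem1 (2.99 ± 0.38) and Lama2 (2.49 ± 0.39) rose. Mesenchymal markers stood at 2.00, 6.56 and 2.03% of their mesenchymal level in the PG epithelium libraries and at 1.00 to 6.20% in those of SMG. Of 13 interstitial matrix genes that rose, 1 had an excess no larger than that share of its PG mesenchyme level.

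Hedgehog genes were 4 higher and 1 lower of 19 (camera adjusted p = 0.0066, adjusted p = 0.58 with an estimated correlation), and 6 higher and 1 lower adjusted over the list alone. Their adjusted p was 8.40e-04 to 0.158 with 1 library left out, the highest without PG epithelium replicate 2. The co-receptor genes Gas1 (3.46 ± 0.30) and Boc (1.23 ± 0.10) and Gli2 (0.81 ± 0.16) rose. Among FGF genes (4 higher and 2 lower of 33; camera adjusted p = 0.91) Fgf8, a ligand of early oral and facial epithelium, rose by 6.40 ± 0.90 and the decoy receptor gene Fgfrl1 fell (-1.12 ± 0.10). The BMP antagonist genes Nog (2.82 ± 0.32) and Chrd (2.92 ± 0.29) rose within a list without a call (camera adjusted p = 0.55). Retinoic acid genes were 4 higher and 5 lower of 19 (camera adjusted p = 0.56), with Aldh1a1 (-2.96 ± 0.45) and Cyp26b1 (-3.15 ± 0.46) lower and Rdh10 (1.94 ± 0.36) higher. Axon guidance and neurotrophic genes were 15 higher and 7 lower of 45 (camera adjusted p = 0.46), with Plxna4 (4.77 ± 0.46) higher and Unc5c (-1.94 ± 0.20) lower. Bud regulators were 6 higher and 4 lower of 32 (camera adjusted p = 0.81). Sox10 was higher by 1.60 ± 0.37 (adjusted p = 0.0128, and 0.0530 without PG epithelium replicate 1). The jaw patterning genes Msx2 (5.91 ± 0.92) and Dlx5 (2.90 ± 0.54) rose, in lists without a call (camera adjusted p = 0.73 for distal and camera adjusted p = 0.15 for proximal genes, the latter 0.0173 to 0.577 with 1 library left out, the lowest without PG epithelium replicate 1).

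Several lists of other cell types were higher in PG epithelium, with PG epithelium replicate 2 highest in most of them. Muscle markers were 7 higher and 0 lower of 24 (camera adjusted p = 3.5e-05, adjusted p = 0.73 with an estimated correlation), and 6 of the 7 had an excess within the mesenchymal share of the libraries. Endothelial markers were 4 higher and 0 lower of 19 (camera adjusted p = 0.0014, adjusted p = 0.92 with an estimated correlation), with adjusted p = 2.71e-09 to 0.769 with 1 library left out, the highest without PG epithelium replicate 2. Schwann and neural crest precursor markers were 3 higher and 0 lower of 12 (camera adjusted p = 0.028, adjusted p = 0.73 with an estimated correlation). Their adjusted p was 6.34e-04 to 0.236 with 1 library left out, the highest without PG epithelium replicate 2, and 0.0603 without SMG epithelium replicate 1. Fabp7, 1 of the 3, went from 6.01 ± 1.34 to 1.52 (adjusted p = 0.122) without PG epithelium replicate 2, and was not past the threshold in a fit of the compared groups alone (0.110) or with limma-trend (0.118). Mesenchymal identity genes were 9 higher and 1 lower of 36 (camera adjusted p = 0.022, adjusted p = 0.92 with an estimated correlation). Without PG epithelium replicate 2 that test turned downward (adjusted p = 0.789), and without SMG epithelium replicate 1 or 4 it was not past the threshold (0.0636 and 0.132). The lowest value with 1 library left out was 7.88e-05. Vim was at 1.02 ± 0.26 (adjusted p = 0.0204), at 0.52 (0.0861) without PG epithelium replicate 2 and at 0.96 without SMG epithelium replicate 2 (0.0587) or 4 (0.0573). It also missed the threshold in a fit of the compared groups alone (0.0950) and with no filter on low counts (0.0639). Cartilage list genes were 3 higher and 0 lower of 13 (camera adjusted p = 0.014, adjusted p = 0.58 with an estimated correlation), with adjusted p = 0.00146 to 0.0519 with 1 library left out, the highest without PG epithelium replicate 1. Counts adjusted over the list alone were 9 higher and 0 lower for muscle, 15 higher and 1 lower for endothelial, 4 higher and 0 lower for Schwann, 10 higher and 2 lower for mesenchymal identity and 7 higher and 1 lower for cartilage genes.

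S phase genes were 0 higher and 5 lower of 42 (camera adjusted p = 0.0058, adjusted p = 0.73 with an estimated correlation) and G2/M genes 0 higher and 4 lower of 52 (camera adjusted p = 0.0033, adjusted p = 0.92 with an estimated correlation). Ccne2 was at -0.69 ± 0.11 and Kif23 at -0.64 ± 0.08. With 1 library left out these adjusted p were 0.00128 to 0.126 and 6.11e-05 to 0.115, both highest without PG epithelium replicate 2. Cholesterol synthesis genes were 0 higher and 2 lower of 24 (camera adjusted p = 0.011, adjusted p = 0.73 with an estimated correlation). Immediate early and stress genes were 1 higher and 1 lower of 33 (camera adjusted p = 0.041, adjusted p = 0.93 with an estimated correlation). This call was lost without SMG epithelium replicate 1, 2 or 3 or PG epithelium replicate 2 or 3 (adjusted p = 0.0517 to 0.284), and was at 1.10e-04 or more with another library left out. With median-ratio factors it was 0.0501. With p adjusted over the list alone, these counts were 0 higher and 5 lower for S phase, 0 higher and 2 lower for G2/M, 0 higher and 0 lower for cholesterol and 0 higher and 1 lower for immediate early genes. In PG epithelium 1339 genes were higher and 882 lower, 11.7% of those tested, and 875 and 384 by an absolute log2 change of at least 1. In 8 lists without a call the median, the mean and the test differed in sign. Without PG epithelium replicate 3 the lower genes numbered 572.

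**Figure D4:**
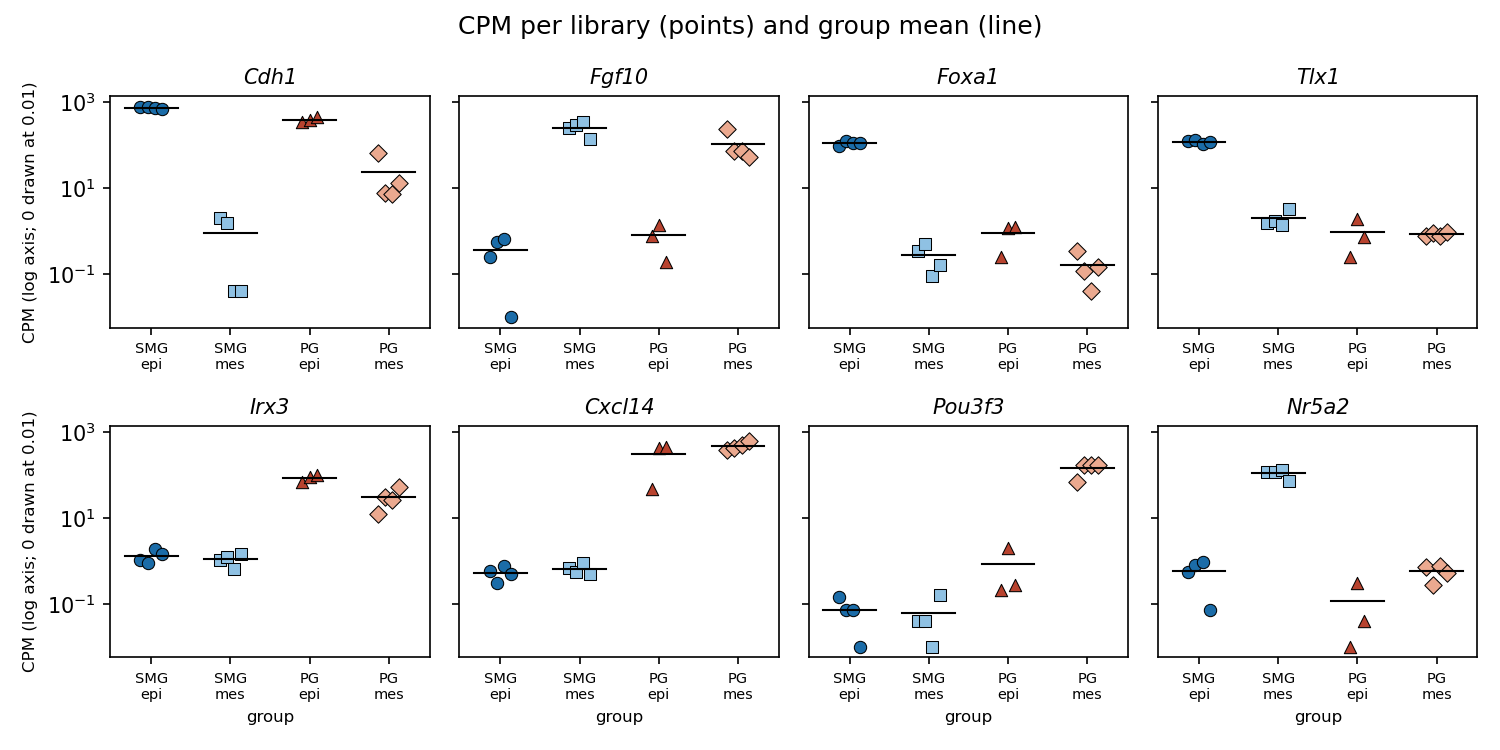
CPM of 8 genes in each library (points, log axis) with the group mean (line). Foxa1 and Tlx1 are above 90 CPM in SMG epithelium and below 5 elsewhere, Irx3 and Cxcl14 are high in both PG groups, Pou3f3 in PG mesenchyme and Nr5a2 in SMG mesenchyme.

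The fourth comparison asked the same of the mesenchyme (n = 4 and 4). Pou3f3, a POU factor gene of the first arch (ENSMUSG00000045515, chromosome 1, 42695768 to 42703176, plus strand), rose from 0.0604 ± 0.0699 CPM in SMG to 142 ± 49.5 in PG mesenchyme (11.07 ± 0.75, adjusted p = 5.65e-07). The neighbouring long non-coding RNA gene Pantr1 on the opposite strand (ENSMUSG00000060424, chromosome 1, 42590782 to 42694842, minus strand) rose by 11.11 ± 0.72, adjusted p = 5.19e-07. Pax1, a paired box gene of endoderm and sclerotome (ENSMUSG00000037034, chromosome 2, 147361925 to 147393295, plus strand), rose from 0.113 ± 0.104 to 118 ± 88.8 CPM (9.97 ± 1.47, adjusted p = 3.40e-04), with 2.76 CPM in PG mesenchyme replicate 1 and 120.2 to 219 in the other 3 libraries. Cxcl14 rose from 0.649 ± 0.188 to 477 ± 102 CPM (9.52 ± 0.74, adjusted p = 2.16e-06). In the other direction the nuclear receptor gene Nr5a2 (ENSMUSG00000026398, chromosome 1, 136842571 to 136960448, minus strand) fell from 109 ± 26.9 to 0.564 ± 0.216 CPM (-7.59 ± 0.49, adjusted p = 2.27e-07). The cartilage proteoglycan gene Acan (ENSMUSG00000030607, chromosome 7, 79053483 to 79115099, plus strand) fell from 28.2 ± 17.2 to 0.145 ± 0.110 CPM (-7.60 ± 0.67, adjusted p = 1.99e-06). Foxc2 (-5.07 ± 0.53) and Klf14 (-4.95 ± 0.36) fell as well. The cadherin gene Cdh8 and the Hox gene Hoxd1 had 1 to 3 counts in SMG mesenchyme, with ratios of 683 (95% counting interval 234 to 3311) and 2168 (95% counting interval 600 to 17901). Fgf10 was not past the threshold (-1.25 ± 0.50, adjusted p = 0.0926), and was at -1.95 (adjusted p = 0.00422) without PG mesenchyme replicate 1 and -1.44 (0.00967) with limma-trend.

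WNT genes were 30 higher and 4 lower of 44 (camera adjusted p = 3.3e-12, adjusted p = 0.13 with an estimated correlation), and 31 higher and 5 lower adjusted over the list alone. Wnt3 (6.59 ± 0.67), Wnt6 (6.28 ± 0.58) and Wnt4 (5.85 ± 0.46) rose, as did Wnt9b (6.61 ± 0.69, and 10.57 without SMG mesenchyme replicate 3). Wnt2b (-4.11 ± 0.44) and the receptor gene Lgr5 (-1.96 ± 0.47) fell. Of 30 WNT genes that rose, 3 (Wnt3 and Wnt9b included) had an excess within the apparent epithelial share of PG mesenchyme. In 9 it was within 2 times that share. Muscle markers were 22 higher and 0 lower of 24 (camera adjusted p = 3.2e-16, adjusted p = 0.26 with an estimated correlation), with Acta1 (6.19 ± 0.68), Tnnc1 (5.13 ± 0.70) and Myh3 (4.93 ± 0.57). Their summed CPM was 165 ± 124 in SMG and 2365 ± 659 in PG mesenchyme. Proximal jaw genes were 8 higher and 1 lower of 16 (camera adjusted p = 5.6e-05, adjusted p = 0.26 with an estimated correlation), with Tbx18 (5.82 ± 0.53), Tbx15 (5.50 ± 0.87) and Shox2 (3.96 ± 0.44). Distal or oral jaw genes split evenly, 7 higher and 7 lower of 24 (camera adjusted p = 0.43), with Msx1 (6.46 ± 0.88) higher and Gsc (-3.23 ± 0.58) lower. Hand2 (-1.92 ± 0.64, adjusted p = 0.0437) was lost without any 1 of the SMG mesenchyme libraries and without PG mesenchyme replicate 3 or 4 (adjusted p = 0.0591 to 0.0986), with no filter on low counts (0.119) and with DESeq2 (0.106). Axon guidance and neurotrophic genes were 19 higher and 6 lower of 45 (camera adjusted p = 5.7e-05, adjusted p = 0.26 with an estimated correlation). Bdnf (4.03 ± 0.72), Sema3e (3.85 ± 0.53) and Ntn1 (3.41 ± 0.36) were higher and Unc5c (-2.95 ± 0.18) lower. The counts adjusted over the list alone were 23 higher and 0 lower for muscle, 9 higher and 1 lower for proximal jaw and 7 higher and 8 lower for distal jaw genes, and the same for axon guidance genes.

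Notch genes were 8 higher and 1 lower of 20 (camera adjusted p = 0.013, adjusted p = 0.45 with an estimated correlation). Hey2 (4.08 ± 0.69), Dll1 (2.05 ± 0.53) and Jag1 (1.94 ± 0.19) were higher, and the non-canonical ligand gene Dlk1 lower (-2.86 ± 0.35). Matrix genes were 15 higher and 6 lower of 36 (camera adjusted p = 0.017, adjusted p = 0.57 with an estimated correlation) and basement membrane genes 11 higher and 3 lower of 30 (camera adjusted p = 0.017, adjusted p = 0.54 with an estimated correlation). Lox (3.12 ± 0.69), Col14a1 (3.76 ± 0.44) and Smoc2 (5.04 ± 0.45) were higher and Lama1 lower (-3.40 ± 0.39). Glycolysis and hypoxia genes were 17 higher and 1 lower of 29 (camera adjusted p = 7.7e-04, adjusted p = 0.43 with an estimated correlation), with Ldha (1.14 ± 0.14) and Egln3 (1.71 ± 0.35). Cholesterol synthesis genes were 18 higher and 0 lower of 24 (camera adjusted p = 1.5e-06, adjusted p = 0.26 with an estimated correlation), with Lss (0.74 ± 0.12). S phase genes were 0 higher and 20 lower of 42 (camera adjusted p = 3.5e-09, adjusted p = 0.17 with an estimated correlation), with Ccne2 (-1.07 ± 0.10) and Mcm3 (-0.51 ± 0.11). G2/M genes were 1 higher and 9 lower of 52 (camera adjusted p = 0.013, adjusted p = 0.68 with an estimated correlation), with adjusted p = 0.00215 to 0.177 with 1 library left out, the highest without PG mesenchyme replicate 1. Adjusted over the list alone, counts were 9 higher and 1 lower for Notch, 18 higher and 6 lower for matrix, 13 higher and 4 lower for basement membrane, 18 higher and 1 lower for glycolysis, 19 higher and 0 lower for cholesterol and 0 higher and 28 lower for S phase genes. Retinoic acid genes were 3 higher and 5 lower of 19 (camera adjusted p = 0.11, and 0.0289 to 0.184 with 1 library left out, the lowest without PG mesenchyme replicate 1), with falls of the receptor gene Rarb (-2.87 ± 0.16) and of Cyp26a1 (-3.69 ± 0.45).

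Epithelial genes were measured at higher levels in PG mesenchyme. Of the epithelial identity list, 31 higher and 0 lower of 36 passed the threshold (camera adjusted p = 1.5e-15, adjusted p = 0.41 with an estimated correlation), and 33 higher and 0 lower adjusted over the list alone. Krt14 had 49.5 ± 25.7 CPM in PG and 0.149 ± 0.165 in SMG mesenchyme (8.29 ± 0.77), Ap1m2 rose by 7.28 ± 0.96 and Cdh1 by 4.67 ± 0.91. Epcam rose by 2.96 ± 0.63, adjusted p = 0.00400, and by 1.69 (adjusted p = 5.75e-05) without PG mesenchyme replicate 1. Of these 31 genes, 22 had an excess no larger than the apparent epithelial share of the PG mesenchyme libraries, which was 18.3% in replicate 1 and 3.29 to 4.07% in the others. Periderm markers were 7 higher and 0 lower of 18 (camera adjusted p = 0.0029, adjusted p = 0.45 with an estimated correlation), and 9 higher and 0 lower adjusted over the list alone, with Gabrp (7.51 ± 0.90). The Iroquois genes Irx1 (6.41 ± 1.01), Irx2 (5.93 ± 0.89) and Irx3 (4.79 ± 0.41) were higher in PG mesenchyme, where Irx3 had 30.2 ± 16.3 CPM. Of other genes followed throughout, Sox9 (1.52 ± 0.31), Fgfr2 (1.72 ± 0.24) and Dlx5 (1.21 ± 0.33) rose. The Sox9 excess was within the epithelial share. Sox10 fell (-1.44 ± 0.36). Dlx5 was lost with no filter (adjusted p = 0.0550). Vim, Pdgfra, Twist1 and Shh did not pass the threshold (adjusted p = 0.191, 0.449, 0.643 and 0.867). In a fit of the mesenchyme libraries alone Pdgfra, Vim and Twist1 did (adjusted p = 6.67e-04, 0.0211 and 0.0398). In all, 2892 genes were higher and 1786 lower in PG mesenchyme, and 1610 and 719 by an absolute log2 change of at least 1. In 2 lists without a call the median, the mean and the test differed in sign.

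The fifth comparison tested for each gene whether the difference between epithelium and mesenchyme was larger or smaller in the PG than in the SMG. Values below 0 mean that the epithelial excess was smaller, or the mesenchymal excess larger, in PG. Acan (9.84 ± 0.98, adjusted p = 1.56e-05) and the monooxygenase gene Cyp1b1 (7.47 ± 0.77, adjusted p = 4.53e-05) had mesenchymal levels in SMG that were not matched in PG. Cyp1b1 had 5.57 ± 2.78 CPM in PG mesenchyme against 142 ± 40.5 in SMG mesenchyme. Negr1 (7.10 ± 0.83), Fmo1 (6.94 ± 0.81) and Cyp2s1 (5.40 ± 0.34) were also above 0. Below 0 stood Pax1 (-13.39 ± 1.98, adjusted p = 6.86e-04), which was epithelial in SMG (9.58 ± 2.44 against 0.113 ± 0.104 CPM) and mesenchymal in PG (0.882 ± 1.39 against 118 ± 88.8 CPM). Dmrt2, a doublesex-related factor gene (ENSMUSG00000048138, chromosome 19, 25672411 to 25678991, plus strand), changed layers in the same way (-9.21 ± 0.67, adjusted p = 1.07e-06), from 39.3 ± 9.63 CPM in SMG epithelium to 12.9 ± 2.67 in PG mesenchyme. Ap1m2 was at -7.22 ± 1.17, adjusted p = 0.00120. Sox10 was above 0 (3.03 ± 0.52, adjusted p = 0.00160), with 95.2 ± 31.7 CPM in PG epithelium and 10.5 ± 4.47 in PG mesenchyme.

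Epithelial identity genes were below 0 in 28 of 36 cases (camera adjusted p = 6.0e-18, adjusted p = 0.52 with an estimated correlation), beside the epithelial share of up to 18.3% in PG mesenchyme, and in 34 cases adjusted over the list alone. Cholesterol synthesis genes were below 0 in 18 of 24 (camera adjusted p = 1.1e-09, adjusted p = 0.34 with an estimated correlation), and in 19 adjusted over the list alone, with Fdps (-1.14 ± 0.23) and Msmo1 (-1.04 ± 0.16). Periderm markers were below 0 in 5 of 18 (camera adjusted p = 0.0062, adjusted p = 0.52 with an estimated correlation), and in 7 adjusted over the list alone. WNT genes were 6 higher and 11 lower of 44 (camera adjusted p = 0.011, adjusted p = 0.52 with an estimated correlation), and 6 higher and 12 lower adjusted over the list alone. Wnt4 (-5.71 ± 0.58) and Dkk1 (-6.36 ± 1.08) were below 0 and Wnt2b above (4.42 ± 0.74). Axon guidance genes were 4 higher and 13 lower of 45 (camera adjusted p = 0.0080, adjusted p = 0.52 with an estimated correlation), and 12 higher and 16 lower alone, with Slit2 (-3.03 ± 0.20) below 0 and Plxna4 (4.01 ± 0.58) above. Notch genes were 1 higher and 6 lower of 20 (camera adjusted p = 0.0080, adjusted p = 0.52 with an estimated correlation), with Jag1 (-2.24 ± 0.28) and Dlk2 (-3.72 ± 0.49). Glycolysis genes were 2 higher and 11 lower of 29 (camera adjusted p = 0.011, adjusted p = 0.52 with an estimated correlation), with Ldha (-1.55 ± 0.21) below 0 and Slc2a3 (3.36 ± 0.31) above. Muscle markers were 0 higher and 4 lower of 24 (camera adjusted p = 0.0080, adjusted p = 0.72 with an estimated correlation), with Myh3 (-4.87 ± 0.83). Cartilage genes were 6 higher and 2 lower of 13 (camera adjusted p = 3.4e-04, adjusted p = 0.34 with an estimated correlation), with Col9a1 (4.91 ± 0.46). Schwann precursor genes were 5 higher and 0 lower of 12 (camera adjusted p = 0.0035, adjusted p = 0.52 with an estimated correlation), Sox10 among them. The counts adjusted over the list alone were 2 higher and 7 lower for Notch, 2 higher and 14 lower for glycolysis, 8 higher and 2 lower for cartilage and 8 higher and 1 lower for Schwann genes, and the same for muscle markers.

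The calls of 4 further lists rested on single libraries. Endothelial markers were 3 higher and 0 lower of 19 (camera adjusted p = 3.4e-04, adjusted p = 0.53 with an estimated correlation), with Ecscr (4.20 ± 0.76) and Pecam1 (2.29 ± 0.43). Their adjusted p was 7.68e-09 to 0.124 with 1 library left out, the highest without PG epithelium replicate 2. Hedgehog genes were 5 higher and 2 lower of 19 (camera adjusted p = 0.014, adjusted p = 0.52 with an estimated correlation), with Gas1 at 2.36 ± 0.38. Their adjusted p was 0.00274 to 0.0849 with 1 library left out, the highest without PG epithelium replicate 2. S phase genes were 6 higher and 0 lower of 42 (camera adjusted p = 0.0080, adjusted p = 0.52 with an estimated correlation), and their adjusted p was 9.01e-04 to 0.0505 with 1 library left out, the highest without PG mesenchyme replicate 1. Proximal jaw genes were 2 higher and 6 lower of 16 (camera adjusted p = 0.014, adjusted p = 0.52 with an estimated correlation). Their adjusted p was 4.62e-07 to 0.0595 with 1 library left out, the highest without PG epithelium replicate 1, and 0.0558 without PG mesenchyme replicate 1. Six2 (-3.52 ± 0.53) was below 0 and Dlx2 (5.11 ± 1.05) above. With p adjusted over the list alone, counts were 13 higher and 0 lower for endothelial, 7 higher and 2 lower for Hedgehog and 7 higher and 0 lower for S phase genes, and the same for proximal jaw genes. In all, 2705 genes passed the threshold, 1130 above 0 and 1575 below, and 762 and 972 of these by an absolute log2 value of at least 1. In 5 lists without a call the median, the mean and the test differed in sign.

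The layer differences of the glands were compared across the 18940 genes, which are not independent replicates. The log2 layer differences correlated at Pearson's r = 0.75 and Spearman's rho = 0.704. Of 6614 genes past the threshold in both glands, 6342 (95.9%) had the same sign. Independent sets of calls would share 1041.3 genes higher in both and 1224.4 lower in both, against 3008 and 3334 observed. The gland differences of the layers correlated less, at r = 0.24 and rho = 0.17. Of 1007 genes past the threshold in both layers, 718 (71.3%) had the same sign, 542 higher in PG in both layers (204.5 if independent) and 176 lower (83.2 if independent). Cxcl14 and Irx3 were higher and Dlk1 (-2.88 ± 0.40 in epithelium) lower in PG in both layers. The comparisons in each pair share no libraries, and the difference between the correlations themselves was not tested.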

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

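The test of PG mesenchyme replicate 1 alone and the fit without both PG epithelium replicate 2 and PG mesenchyme replicate 1 were chosen only after the results were seen.

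Epithelial identity genes were higher in PG than in SMG mesenchyme, with 31 of 36 past the threshold. The tables argue against the scaling factors, since 31 were called with median-ratio factors, and against PG mesenchyme replicate 1 alone, without which 29 were called. RNA of PG epithelium carried into these libraries stays a candidate explanation. Of 61 epithelium-specific genes outside the list, 90.2% had a ratio of PG mesenchyme to PG epithelium within a factor of 2 of the list's median of 7.40%, and 22 of the 31 genes had an excess no larger than the carried share (30 no larger than 2 times it). Expression of these genes by PG mesenchyme cells, or a difference between the stages, also stays open and was not tested, since gland and embryonic day change together.

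In both layers more genes were higher than lower in PG, 60.3% of the calls in epithelium and 61.8% in mesenchyme. The excess was within the carried share in 2.32% of 1339 genes higher in PG epithelium and 4.01% of 2892 higher in PG mesenchyme. For 94 and 413 it was within 2 times the share, so RNA of the other layer stays a candidate for these. With every library thinned to the lowest total, 63.0% (1351 against 795) and 62.0% (2851 against 1750) of calls were higher. That argues against unequal depth. A difference between glands or stages stays open, untested.

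WNT pathway genes were higher in PG than in SMG epithelium, 20 of 44 past the threshold. An excess within the share of mesenchymal RNA in PG epithelium was found in 0 of the 20 (2 within 2 times it). The share is a median, so carried genes can exceed it. With any 1 epithelial library left out at least 16 of the 20 were still past the threshold, the fewest without SMG epithelium replicate 2 or PG epithelium replicate 2, which argues against a single library as the source. A change of WNT signalling with gland or stage stays open as a hypothesis. The list's call was lost with an estimated correlation (adjusted p = 0.43).

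Other groupings of the libraries were fitted in the same way. The labels gave 9826 genes in the SMG layer comparison (highest other 1), 8721 in the PG layer comparison (4388), 2221 between epithelia (374) and 4678 between mesenchymes (12), in each case the 1 split of 35 with so many. For the interaction, 100 splits with gland labels permuted within each layer gave at most 2056 genes apart from the real 2705. In all 5, no other split gave as many calls.

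Some libraries lay far from the other libraries of their group by Dixon's criterion, which chance meets in about 1 in 20 groups. Of 18 groups of library measures 3 held such a library (0.90 by chance), of 96 groups of list scores 10 (4.8) and of 51 groups of single genes 8 (2.5). PG epithelium, with 3 libraries, was not tested. The apparent share of the other layer was 18.3% in PG mesenchyme replicate 1 (others 3.29 to 4.07%) and 6.20% in SMG epithelium replicate 3 (others 1.00 to 1.68%). Mitochondrial genes took 0.689% of the counts in SMG mesenchyme replicate 3 (others 1.10 to 1.18%). In PG mesenchyme replicate 1 the mean log2 CPM of epithelial identity genes was 4.41 (others 1.97 to 2.36), of periderm markers 1.15 (-0.440 to -0.280), of retinoic acid genes 4.77 (4.34 to 4.39) and of S phase genes 6.53 (6.67 to 6.68). The same library had 66.3 CPM of Cdh1 (7.16 to 12.9), 92.1 of Epcam (12.2 to 16.0), 6.63 of Foxe1 (0.75 to 1.05), 90.5 of Sox9 (34.1 to 39.6), 233 of Fgf10 (52.2 to 75.1), 300 of Aldh1a2 (106 to 125) and 67.7 of Pou3f3 (166 to 167). SMG mesenchyme replicate 4 had mean scores of 4.69 for BMP and TGF-beta genes (4.30 to 4.34) and 3.73 for distal jaw genes (3.46 to 3.50), and SMG epithelium replicate 3 had 3.35 for Notch genes (3.11 to 3.14). Steap4 had 0.712 CPM in SMG mesenchyme replicate 1 (0 to 0.0862). The mean log2 CPM of Xist and 4 Y-linked genes was -1.29 in SMG epithelium replicate 4 (4.79 to 5.73), -1.11 in SMG mesenchyme replicate 4 (4.62 to 5.77) and -1.45 in PG mesenchyme replicate 2 (4.78 to 5.89).

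The interaction test called 2705 genes. Leading genes above 0 were Acan (log2 9.84), Cyp1b1 (7.47), Negr1 (7.10), Fmo1 (6.94), Steap4 (5.58), Cyp2s1 (5.40), Nr5a2 (5.33) and Ntrk2 (5.31). Below 0 were Pax1 (-13.39), Cdh8 (-9.91), Dmrt2 (-9.21), Sptssb (-7.67), Krt6a (-7.64), Pou3f3 (-7.63), Scel (-7.36) and Ap1m2 (-7.22). Values of genes with few or no counts in a group depend on the prior count. Of 1180 genes below 0 and higher in PG mesenchyme, 74 (Ap1m2 included) had an excess within the epithelial share (200 within 2 times it). A further 188 named genes passed, 71 above and 117 below 0. The calls of 3 leading genes depended on single libraries. Nr5a2 was at 3.04 (adjusted p = 0.635) without PG epithelium replicate 2 and Steap4 at 2.94 (0.528) without SMG mesenchyme replicate 1. Pou3f3 was lost without replicate 1, 2 or 3 of SMG epithelium or mesenchyme (0.0607 to 0.166). With no filter all 3 were lost (0.0732, 0.0716 and 0.102). So was Nr5a2 without both PG epithelium replicate 2 and PG mesenchyme replicate 1 (0.632). Over all alternatives the adjusted p ran from 2.44e-08 to 0.635 for Nr5a2, 1.49e-04 to 0.528 for Steap4 and 2.02e-07 to 0.166 for Pou3f3. Of the gene lists, the camera adjusted p of the interaction was 6.0e-18 for epithelial identity, 1.1e-09 for cholesterol synthesis, 3.4e-04 for endothelial and for cartilage markers, 0.0035 for Schwann precursor and 0.0062 for periderm markers. It was 0.0080 for Notch, axon guidance, muscle and S phase genes, 0.011 for WNT and glycolysis genes and 0.014 for Hedgehog and proximal jaw genes. With an estimated correlation none of these was called (adjusted p = 0.34 to 0.72).

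ERCC spike-in RNA, which entered no comparison, drew 371 to 1314 counts per library.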

How the results depend on the processing

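The fit without both PG epithelium replicate 2 and PG mesenchyme replicate 1, the test on reads recovered from the deposited CPM, the similarity of the gland differences at a mean CPM of at least 5 and both similarities with 1 library left out were chosen only after seeing the data. No gene called in a comparison was called in the opposite direction under any alternative fit of that comparison. Median-ratio factors kept 96.3 to 99.5% of the calls of the 5 comparisons, DESeq2 96.7 to 98.8%, limma-trend 89.0 to 97.3%, no filter 79.5 to 91.7%, the compared groups alone 78.2 to 91.3% of 4 comparisons and the fit without both libraries 77.4 to 97.7%. Recovered reads gave identical calls. For the interaction, a fit of the compared groups alone is the fit of all 4 groups, so it has no value of its own. With 1 library left out the SMG layer comparison had 4153 to 4680 genes higher and 4684 to 5030 lower, the PG layer comparison 3431 to 4171 and 4032 to 4635, the epithelia 1049 to 1445 and 572 to 788, the mesenchymes 2350 to 2746 and 1371 to 1710, and the interaction 2185 to 2744. The 572 genes, without PG epithelium replicate 3, were the 1 count of genes past the threshold that moved by over 1.5 times, and the cause was not tested. Of genes also changed by an absolute log2 of at least 1, limma-trend counted 2023 lower between the SMG layers (against 3169), 544 higher between the epithelia (875) and 424 lower between the mesenchymes (719), on a log2(CPM + 1) scale that understates the change of low genes. Under the other alternatives the counts were 4514 to 4765 and 4724 to 5696, 3401 to 4286 and 3950 to 4844, 1158 to 1875 and 671 to 1031, 2481 to 3129 and 1606 to 2155, and 1979 to 3450, in the same order. An estimated correlation left 0, 1, 0, 0 and 0 gene lists called, against 15, 18, 13, 13 and 14 with the preset one, and the cause was not tested. In the comparison of epithelia, 7 to 14 lists were called with 1 library left out, the fewest without PG epithelium replicate 2, and 8 without both libraries, and the cause was not tested. The mesenchymal identity list there had an adjusted p of 7.88e-05 to 0.789 with 1 library left out and 0.753 without both, turning downward in the latter and without PG epithelium replicate 2. Pearson's r of the layer differences was 0.83 at a mean CPM of at least 5, against 0.75, and 0.72 to 0.759 with 1 library left out. For the gland differences it was 0.283, against 0.24, and 0.169 to 0.245, the lowest without PG epithelium replicate 2. The cause of these shifts was not tested.

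Of the named genes, 5 turned in 1 comparison each. In the interaction, limma-trend put Myog at -3.02 (adjusted p = 0.00697, 0.00697 to 1.000 over all alternatives), against 0.35, and Gabrp at 0.16 (0.885, 9.44e-04 to 0.885), against -3.98. Fabp7 between the PG layers was at -3.41 (1.89e-04) without PG epithelium replicate 2 and up to 1.67 without another library, and at -3.12 without both libraries (1.89e-04 to 0.569 over all alternatives). Shh between the epithelia was at -3.28 (0.0419) without PG epithelium replicate 2 and up to 1.67, and at -3.28 without both (0.0401 to 0.934). Cdh3 between the mesenchymes was at -0.82 (0.00954) without PG mesenchyme replicate 1 and up to 0.33, and at -0.82 without both (0.00954 to 1.00). Apart from the libraries left out, the cause was not tested. Depth limits genes with few reads, as 1 read is worth a median of 0.039 CPM, and the ratio of Shh between the PG layers had an interval of 15.2 to 3336.

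Replicate numbers were not taken to pair the samples, since not every pair correlated above 0.1. Deviations from the group means of the 2 layers with the same number correlated at r = 0.01, 0.14, 0.19 and 0.28 in SMG and 0.07, 0 and -0.12 in PG, and those of the 2 glands at 0.09, 0.03 and -0.1 in epithelium and 0.03, -0.07, 0.07 and 0.06 in mesenchyme. SMG numbers 2, 3 and 4 correlated best with their own number, and number 1 did not (0.03 with another). With a replicate block there were 4765 genes higher and 4960 lower between the SMG layers, 3639 and 4286 between the PG layers, 1158 and 803 between the epithelia, 2894 and 1795 between the mesenchymes and 1979 in the interaction. These fits kept 94.4, 86.9, 82.2, 94.1 and 67.0% of the calls, and no count moved by over 1.5 times. They called 16, 20, 11, 14 and 13 lists. Lists gained were FGF between the SMG layers (adjusted p = 0.0102), WNT (0.0405) and mitochondrially encoded genes (0.0114) between the PG layers and bud regulators between the mesenchymes (0.0435). Lists lost were mesenchymal identity (0.0565) and Schwann precursor markers (0.0646) between the epithelia and WNT in the interaction (0.0823). Of genes given above, Vim (0.0784) and Fabp7 (0.105) were lost between the epithelia and Fgf10 was gained between the mesenchymes (0.0424). In the interaction Nr5a2 (0.0721), Steap4 (0.0645), Pou3f3 (0.0582) and Ntrk2 (0.171, 1.06e-04 to 0.171 over all alternatives) were lost, Ntrk2 under no other alternative.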

Other observations

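The fit without both PG epithelium replicate 2 and PG mesenchyme replicate 1 was chosen, and the single libraries given below were picked out, only after the results were seen. Hox genes were read mainly in PG mesenchyme. Their summed CPM was 55.5 ± 46.9 there (n = 4), 5.47 ± 2.33 in SMG epithelium (n = 4), 2.35 ± 1.87 in SMG mesenchyme (n = 4) and 1.27 ± 1.24 in PG epithelium (n = 3). In PG mesenchyme replicate 1 it was 1.3, against 43.1, 63.3 and 114.3 in the other libraries. Of 32 members 7 had enough counts to be tested, and they were 3 higher and 1 lower of 7 in PG mesenchyme (3 higher and 2 lower over the list alone), Hoxd8 among the higher ones (3.99 ± 0.91). The list had no call (camera adjusted p = 0.90) until both PG epithelium replicate 2 and PG mesenchyme replicate 1 were left out (adjusted p = 0.0144, against 0.336 to 0.960 with 1 library left out, the highest without SMG mesenchyme replicate 1). Osteogenic markers were 5 higher and 1 lower of 8 in PG mesenchyme (camera adjusted p = 0.21; the same over the list alone), with the bone factor gene Runx2 (1.87 ± 0.44) and the phosphatase gene Alpl (2.40 ± 0.38). Their summed CPM was 72.5 ± 34.8, with 30.9 in replicate 1 and 66.2 to 115.4 in the others, against 25.4 ± 6.31 in SMG mesenchyme.

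Growth factor genes changed in PG mesenchyme in lists that had no call. FGF genes were 14 higher and 5 lower of 33 (camera adjusted p = 0.12), with the receptor gene Fgfr4 (2.88 ± 0.41) and Fgf9 (2.68 ± 0.29) higher and Fgf7 (-1.89 ± 0.38) and the FGF target gene Etv4 (-2.13 ± 0.20) lower. BMP and TGF-beta genes were 14 higher and 7 lower of 37 (camera adjusted p = 0.27), with Bmp3 (4.03 ± 0.68) and Nog (3.07 ± 0.33) higher and Bambi (-1.66 ± 0.18) lower. Salivary bud regulators were 15 higher and 6 lower of 32 (camera adjusted p = 0.10), and 5 of the 15 higher ones had an excess no larger than the apparent epithelial share. With 1 library left out the FGF list was called without PG mesenchyme replicate 4 (0.0491, 0.0491 to 0.206 over the libraries) and the bud regulators without PG mesenchyme replicate 3 (0.0265) or 4 (0.0282), with at most 0.191 without another. Counts adjusted over the list alone were 14 higher and 7 lower for FGF, 15 higher and 8 lower for BMP and TGF-beta and 15 higher and 7 lower for bud regulators.

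Neuronal markers summed to 583 ± 250 CPM in PG and 221 ± 36 in SMG mesenchyme, with 946.4 in PG mesenchyme replicate 1. Of 16 tested, 1 was higher and 3 lower in PG mesenchyme (camera adjusted p = 0.41; 1 higher and 4 lower over the list alone). In epithelium they summed to 280.3 CPM in PG replicate 2, to 29.9 and 22.2 in the other PG libraries and to 63.4 ± 6.86 in SMG. The list was 3 higher and 1 lower of 16 between the epithelia, without a call (camera adjusted p = 0.41), and was called without PG epithelium replicate 1 (0.0268) or 3 (0.00726). Its adjusted p was 0.00726 to 0.530 with 1 library left out, the highest without SMG epithelium replicate 1. Between the PG layers (camera adjusted p = 0.75) it was called without PG epithelium replicate 2 (0.00210), and its adjusted p was 0.00210 to 0.834 with 1 library left out, the highest without PG epithelium replicate 1. Mitochondrially encoded genes were 0 higher and 5 lower of 10 in SMG epithelium (camera adjusted p = 0.29) and 0 higher and 5 lower of 10 in PG epithelium (camera adjusted p = 0.097) relative to mesenchyme. That list had no call between the epithelia (camera adjusted p = 0.062) or the mesenchymes (camera adjusted p = 0.31). With 1 library left out it was called between the epithelia without SMG epithelium replicate 1 or 3 (0.0312 and 0.0303) or PG epithelium replicate 2 (0.00154), and between the PG layers without PG epithelium replicate 2 (0.0178). The highest adjusted p with 1 library left out were 0.361 and 0.218. The list of Xist and 4 Y-linked genes had no call in any comparison (camera adjusted p = 0.79 to 0.97).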
